A study of Mus musculus with 9 samples.

How the data were processed

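Cerebral cortex from E13.5 mouse embryos was used, with 3 libraries each of control, Sfpq heterozygous and Sfpq homozygous embryos. Per the labels' protocols, total RNA was extracted with a column kit, ribosomal RNA was removed with Ribo-Zero and strand-keeping libraries were sequenced on a HiSeq2000. Per the submitters' processing notes, CASAVA 1.8.2 and TopHat 1.4.1 were used with the genome build mm9. The program that made the expression values, its annotation version, its use of strand and its treatment of reads that map to several places are not given in the sources used here. Values of overlapping, antisense or near-identical genes (histones, globins) are therefore uncertain.

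The authors deposited 1 table per library with an RPKM value for each of 30978 RefSeq transcripts, per the file headers. RPKM is the number of reads per kilobase of transcript and per 1e6 reads, so library size and transcript length are already divided out. RPKM times exonic length, summed over 1 transcript per gene, came to 0.742 to 0.792 (in 1e6) per library, and times genomic span to 6.94 to 8.17 (in 1e6), so the length used was the exonic one. The files give no counts. Low values fell mostly on whole multiples of a step: 64.1% to 68.5% of values worth under 5 reads lay within 0.1 of a whole read, which gives an estimated depth of 170 M to 205 M reads (M, 1e6) per library. The lengths behind this estimate come from another annotation than the authors', so it is approximate, and no count test was run.

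Transcripts were named with a RefSeq gene table (30507) and the GENCODE M21 table of RefSeq identifiers (178), and 293 had no name. Exonic length, genomic span, GC content and chromosome came from GENCODE M21 on GRCm38. This is not the authors' build, so no coordinates are given and spans are those of GRCm38. Each of 23201 genes was represented by 1 transcript, coding before non-coding, then the one with the largest span, the longest exonic length and the higher mean; 22839 genes had a length. The choice of coding before non-coding was made after the files were seen, and other choices of transcript are among the alternatives.

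All 9 libraries were fitted together with limma 3.58.1 in R 4.3.3 (linear model by genotype, empirical Bayes with a mean-variance trend) on log2(RPKM + 0.5), using the 12129 genes with a mean of at least 0.5 RPKM over the 9 libraries. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. The median standard error of a log2 change was 0.0822, and 45.9% of genes had no overlap between homozygous and control libraries, where chance gives 10%. Gene length was tested by the difference of median log2 changes between genes of at least 100 kb and shorter ones, with camera (preset correlation between genes of 0.01, and an estimated correlation beside it), and with a two-sided exact permutation test of 1 value per library, whose smallest p for 3 against 3 is 0.1. The 30 gene lists, 928 of 939 entries of which were matched when a list of sex-linked genes is counted, were written from textbook knowledge before the data were examined, as were the test designs and the alternatives not marked as added. Lists were tested with camera in the same way and with fry, adjusted over the 30 lists. All list calls were made with the preset correlation; fry, which does not compare a list with other genes, gave an adjusted p of 6.97e-05 for the very long neuronal genes in homozygous against control cortex and 0.995 in heterozygous against control cortex.

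Genes named in the text follow a rule fixed before the data were examined: Sfpq; for each comparison up to 12 genes with the largest rise and 12 with the largest fall among those called, with a mean of at least 1 RPKM in the higher group and no overlap between the groups; up to 4 members of each list with the smallest adjusted p in homozygous against control cortex, and the best known marker of the list; 12 genes of at least 100 kb and 6 of at least 200 kb with the smallest adjusted p. Xist and Y-linked genes served only to read the sex of each library. Some genes are in more than 1 list. Values of a few genes that this rule takes are not reported here.

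The test was run on simulated data with the gene means and spreads of homozygous against control cortex, 12129 genes, 200 of them changed, in 10 runs. It found 88.2% of genes changed by 0.5 and 99.7% of those changed by 1 on the log2 scale, with 4.96% of calls false. A simulated shift of long genes was found in 10 of 10 runs and an absent one in 0 of 10. In these runs genes varied independently and camera used the preset correlation. The estimated correlation among the measured long genes was 0.282, so the runs do not test false calls at that correlation. No 2 libraries held the same table, and the SD of the log2 difference between libraries of a group was at least 0.148. Embryos are the replicates, so the p-values of limma and of the exact permutation tests measure the spread between embryos. Camera with the preset correlation compares genes with other genes, and Fisher's exact test counts genes. Their p-values do not measure that spread.

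Alternatives were other pseudocounts (0.1 and 1), no filter and a filter at 2 RPKM, median-ratio scaling, quantile normalization, a fit of only the groups compared, no variance trend, the replicate number as a block, length limits of 50 and 200 kb, short genes matched on expression, and leaving out each library in turn. Added after the data were examined were other choices of transcript, embryo sex in the model, short genes matched on exonic length, and a fit of protein-coding genes minus histones. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.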

Results

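RNA was measured in the cerebral cortex of E13.5 mouse embryos, a stage at which radial glia divide along the ventricle and the first cortical neurons form. The series asks how loss of Sfpq, a nuclear RNA-binding protein of the DBHS family whose other members are Nono and Pspc1, changes the expression of long neuronal genes. There were 9 libraries, each from a separate embryo: 3 control, 3 heterozygous for the Sfpq mutation and 3 homozygous. Ribosomal RNA was removed and total RNA kept, so that transcripts with and without a poly(A) tail were read. The steps between low values gave an estimated depth of 176 M, 205 M and 172 M reads for the control libraries (M, 1e6 reads), 177 M, 182 M and 190 M for the heterozygous and 170 M, 177 M and 196 M for the homozygous libraries. Levels are RPKM values, and log2 changes are differences of log2(RPKM + 0.5), which understate the change of genes with low values. Read from Xist and 4 Y-linked genes, the control embryos were 2 females and 1 male, the heterozygous embryos 3 males, and the homozygous embryos 1 female and 2 males.

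Sfpq itself was at 168, 187 and 201 RPKM in the control libraries, at 168, 149 and 151 RPKM in the heterozygous libraries and at 23.8, 25.7 and 25.4 RPKM in the homozygous libraries. The homozygous mean of 24.96 ± 1.06 RPKM (SD, n = 3) was 13.48% of the control mean of 185 ± 16.8 RPKM (SD, n = 3). The log2 change was -2.86 ± 0.07 (SE), with a limma adjusted p of 1.64e-09, and a two-sided exact permutation test of the RPKM values gave p = 0.1, the smallest that 3 against 3 libraries allow. The heterozygous mean of 156 ± 10.6 RPKM (SD, n = 3) was 84.2% of control, with a log2 change of -0.25 ± 0.07 (SE) that did not pass (limma adjusted p = 0.658; exact permutation p = 0.2). Which part of the gene the mutation removes is not given in the sources used here, so the remaining 13.48% can include reads from the part that is kept. Pspc1, another DBHS family member, went the other way: it was at 102 ± 1.59 RPKM in control, 133 ± 8.26 RPKM in heterozygous and 262 ± 11.1 RPKM in homozygous cortex (SD, n = 3 each).

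**Figure D1:**
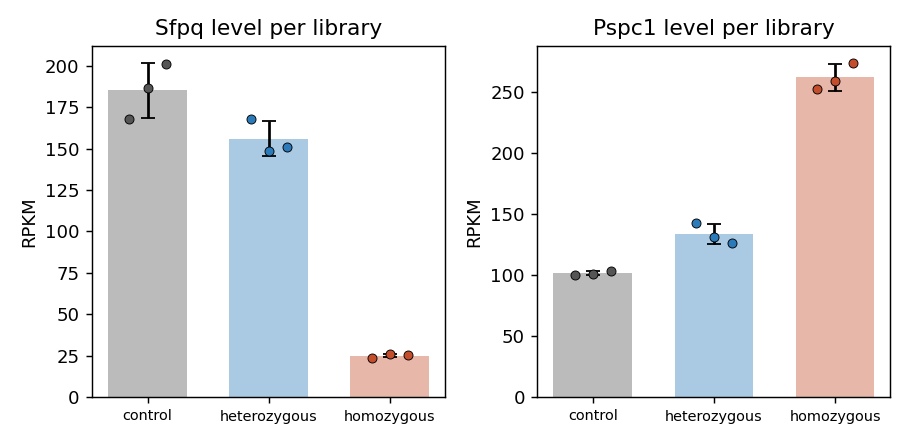
RPKM (vertical axis, from 0) of Sfpq and Pspc1 in each of the 9 libraries, by genotype; bars are group means, error bars the SD of 3 libraries and points single libraries. The homozygous libraries sit at 23.8 to 25.7 RPKM for Sfpq, below all controls, and at 252 to 274 RPKM for Pspc1, above all controls.

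The first comparison asks what loss of both Sfpq copies changes. In homozygous cortex 58 of 67 very long neuronal genes fell (list adjusted p = 0.557 with an estimated correlation). Long genes that fell include the netrin receptor Dcc, the cell adhesion partner Ctnna2 (alpha-N-catenin), the glutamate receptor subunit Grik2 and the transcription factor Npas3. Of the cell cycle genes 22 of 30 and of the replication-dependent histone genes 52 of 62 fell, by smaller amounts (list adjusted p = 0.720 each with an estimated correlation). Genes that rose included Th, the rate-limiting enzyme of catecholamine synthesis, the retinoic acid binding protein Crabp2, the calcium-binding protein Calb1, Pspc1, 11 of 27 p53 targets, 6 of 10 markers of Cajal-Retzius cells and 6 of 14 of microglia (list adjusted p = 0.720 each with an estimated correlation). Of 12129 genes tested, 4134 changed (limma, Benjamini-Hochberg adjusted), 1723 higher and 2411 lower in homozygous cortex. At least 2-fold changes were seen for 81 of the higher and 270 of the lower genes. Quantile normalization moved the split of all changed genes to 2558 higher and 2149 lower.

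Apart from Sfpq, the steepest falls were in genes of large genomic span. Mpped2, a metallophosphoesterase gene spanning 175 kb, fell from 19.8 ± 0.754 to 2.90 ± 0.130 RPKM (SD, n = 3, log2 change -2.58 ± 0.08 SE, adjusted p = 9.86e-09). Dcc, which guides commissural axons and spans 1097 kb, fell from 10.1 ± 0.476 to 1.44 ± 0.106 RPKM (log2 change -2.45 ± 0.10 SE, adjusted p = 3.06e-08). Ctnna2, which links cadherins to actin in neurons and spans 1098 kb, fell from 29.0 ± 1.28 to 5.47 ± 0.990 RPKM (log2 change -2.32 ± 0.11 SE, adjusted p = 1.01e-07). Ankrd6, a regulator of Wnt signalling, fell by 2.55 on the log2 scale, the heparan sulfate sulfotransferase gene Hs6st2 by 2.37, the non-coding gene E130307A14Rik by 2.34, the DNA sensor gene Aim2 by 2.26, Npas3 by 2.25, the potassium channel partner Kcnip1 by 2.22, the homeobox gene Meis2 by 2.14 and Tmem132b by 2.13. All 11 span more than 100 kb in the GRCm38 annotation. Other genes of at least 100 kb with the smallest adjusted p were Nsmce2, a SUMO ligase gene, at a log2 change of -1.97, the neural RNA-binding protein Msi2 at -2.01, Cmss1 at -1.98, Slc35f1 at -2.08, the semaphorin Sema5b at -2.10, adenosine kinase Adk at -1.83 and Gas2 at -2.11. In each of these genes the 3 homozygous libraries lay below all 3 controls, which the naming rule required of the 11 steepest falls. Over all genes tested, 45.9% had no overlap between these groups.

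Th rose from 0.323 ± 0.214 to 5.40 ± 1.05 RPKM (SD, n = 3, log2 change 2.86 ± 0.18 SE, adjusted p = 5.63e-07) and Crabp2 from 37.7 ± 4.18 to 165 ± 15.2 RPKM (log2 change 2.12 ± 0.09 SE, adjusted p = 3.06e-08). Calb1 rose by 2.04 on the log2 scale, from 1.87 ± 0.258 to 9.47 ± 2.67 RPKM, and Olig3, a transcription factor of dorsal progenitors outside the cortex, by 2.15, from 0.0184 to 1.82 RPKM. The other large rises were Cep295nl at 2.32, the uridine phosphorylase Upp1 at 2.07, Samd3 at 1.95, the epithelial gene Scel at 1.95, Mab21l1 at 1.90, Gm10421 at 1.89, the axon guidance receptor Robo3 at 1.83 and Pdlim3 at 1.83. Their spans ran from 2.1 kb for Olig3 to 99.4 kb for Scel.

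Length was then taken over all genes, which is the question the series names. The 1640 genes spanning at least 100 kb had a median log2 change of -0.16 in homozygous against control cortex, and the 10389 shorter genes one of 0.00. Of the long genes 706 fell and 158 rose; of the shorter genes 1694 fell and 1553 rose. The share that fell grew with span above 30 kb: 15.2% of genes under 10 kb, 14.4% of those of 10 to 30 kb, 19.5% of those of 30 to 100 kb, 32.3% of those of 100 to 200 kb and 60.2% of the 633 genes of 200 kb and over were lower. In the class of 500 kb and over, a division added after the values were seen, 87 of 119 genes were lower and 2 higher, with a median of -0.68. Per library, the long-minus-short median against the control mean was 0.000 ± 0.0434 in control and -0.189 ± 0.0281 in homozygous cortex (SD, n = 3; exact permutation p = 0.1, the smallest possible). Camera, which compares a set of genes with the rest, gave p = 4.80e-11 for the difference with a preset correlation between genes and p = 0.248 with an estimated correlation.

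**Figure D2:**
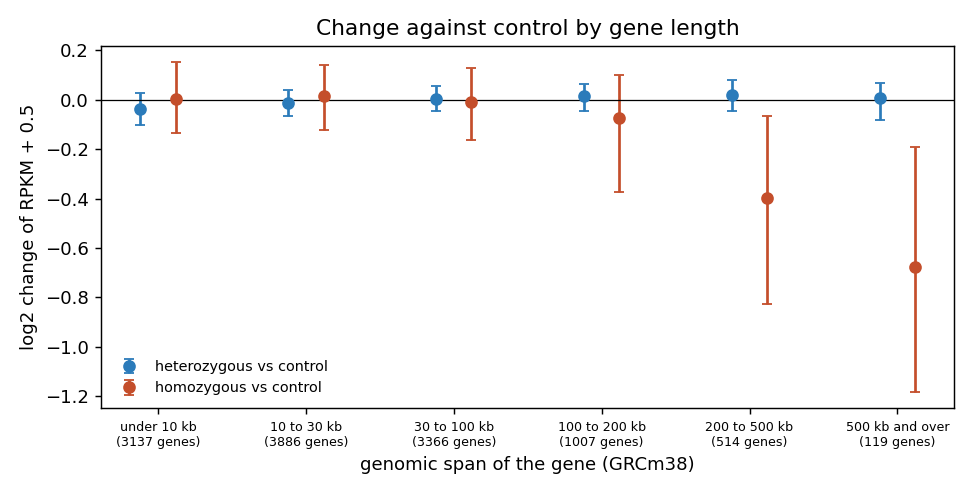
Median log2 change of RPKM + 0.5 against control (vertical axis) by genomic span of the gene (horizontal axis), for heterozygous and homozygous embryos; points are medians over genes and bars the range from the lower to the upper quartile. Homozygous medians fall from -0.07 at 100 to 200 kb to -0.40 at 200 to 500 kb and -0.68 at 500 kb and over, and heterozygous medians stay between -0.04 and 0.02.

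Of the list of very long neuronal genes, 58 of 67 fell and 1 rose, with a median log2 change of -1.07 (59 lower and 3 higher adjusted over the list alone, camera adjusted p = 9.90e-26, adjusted p = 0.557 with an estimated correlation). Grik2 fell by 1.96 on the log2 scale, Khdrbs2, a splicing regulator, by 2.12, and the adhesion molecule Cadm1 by 1.91. Axon guidance genes fell in 29 of 53 cases and rose in 8 (median -0.41; 29 and 8 adjusted over the list alone, camera adjusted p = 1.57e-05, adjusted p = 0.720 with an estimated correlation). The ephrin receptor Epha5 fell from 30.2 ± 3.71 to 7.06 ± 0.450 RPKM (SD, n = 3) and Ephb1 by 1.63 on the log2 scale. By span, 23 of the 31 axon guidance genes of at least 100 kb were lower, with a median of -0.89, against 6 of 22 shorter ones, with a median of -0.07. Neuronal ion channels and receptors fell in 17 of 30 cases and rose in 2 (median -0.41; 18 and 3 adjusted over the list alone, camera adjusted p = 1.84e-04, adjusted p = 0.720 with an estimated correlation). The potassium channel Kcnd3 fell by 1.67, the calcium channel subunit Cacna2d1 by 1.18 and the glutamate receptor Gria4 by 1.35. Of 49 genes for synaptic adhesion and the active zone 21 fell and 5 rose (median -0.16; 21 and 5 adjusted over the list alone, camera adjusted p = 0.00368, adjusted p = 0.831 with an estimated correlation). The neuroligin Nlgn1 fell by 1.86 and the vesicle priming gene Cadps by 1.74. In this list the 23 long members had a median of -0.56 and the 26 shorter ones 0.01.

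Cortical cell type markers moved less evenly. Of 26 markers of cortical excitatory neurons 9 fell and 3 rose (9 and 3 adjusted over the list alone), which as a set did not pass (median -0.10, camera adjusted p = 0.164, but 0.0172 without homozygous library 3). The pan-neuronal splicing factor Rbfox3 fell by 1.27, the vesicle calcium sensor Syt1 by 0.94, and the layer 5 regulator Fezf2 by 0.60 on the log2 scale, while the early neuronal factor Tbr1 rose from 5.91 ± 0.516 to 7.41 ± 0.290 RPKM (SD, n = 3, limma adjusted p = 0.0102). Rbfox3 and Syt1 span 420 and 513 kb. Of the 18 excitatory markers under 100 kb 4 fell and 3 rose (median -0.06), and of the 8 longer ones 5 fell and 0 rose (median -0.36). Of 18 markers of intermediate progenitors 7 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 0.0799, but 0.0263 with no filter, 0.0468 with sex in the model and 0.0397 without control library 1). The short proneural gene Neurog2 fell from 62.4 ± 4.43 to 24.5 ± 3.71 RPKM (log2 change -1.34 ± 0.11 SE, adjusted p = 3.65e-06), Insm1 fell by 0.76 and Eomes by 0.50. Of 21 radial glia markers 9 fell and 2 rose (10 and 2 adjusted over the list alone, median -0.24, camera adjusted p = 0.0446, adjusted p = 0.720 with an estimated correlation). Ddah1 fell by 1.78, Prom1 by 0.67 and Lhx2 by 0.68 on the log2 scale, and Pax6 was at 28.8 ± 4.13 and 29.1 ± 1.43 RPKM (adjusted p = 0.873). Ddah1 and Prom1 span 136 and 108 kb. Of the 19 radial glia markers under 100 kb 7 fell and 2 rose (median -0.09), and the 2 longer ones both fell (median -1.22). The radial glia call was lost without control library 3 (adjusted p = 0.0956), without homozygous library 3 (adjusted p = 0.0698) and at a mean of at least 2 RPKM (adjusted p = 0.0680). Of 17 markers of GABAergic neurons 3 rose and 3 fell (3 and 3 adjusted over the list alone, median -0.05, test direction up, camera adjusted p = 0.874). Gad1 and the chemokine receptor Cxcr4 were higher and Erbb4, a neuregulin receptor spanning 1076 kb, lower.

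Of 10 Cajal-Retzius markers 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 0.00985, adjusted p = 0.720 with an estimated correlation): Lhx5 rose by 1.16 on the log2 scale, Barhl2 by 1.09, Nhlh2 by 1.02 and Ebf2 by 0.89. Reln, the signal these cells secrete, was at 16.8 ± 1.88 RPKM in control and 14.9 ± 0.354 RPKM in homozygous cortex (SD, n = 3, limma adjusted p = 0.149, but 0.0172, and lower, without control library 1). Of 10 markers of the diencephalon and hem 4 rose, Lhx9, Tcf7l2, Otx2 and Rspo3 (4 adjusted over the list alone), and as a set they did not pass (median 0.05, camera adjusted p = 0.255, but 0.0263 with no filter). The Rspo3 call was lost with no filter (limma adjusted p = 0.0539) and without control library 1 or 2 or homozygous library 1 or 2 (limma adjusted p = 0.0539 to 0.0737). Of 14 microglia and macrophage markers 6 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 0.00107, adjusted p = 0.720 with an estimated correlation). The complement gene C1qb rose from 2.94 ± 0.0930 to 4.33 ± 0.572 RPKM and C1qa rose from 3.14 ± 0.0389 to 4.67 ± 0.838 RPKM (SD, n = 3). The mean of the microglia list lay 0.24, 0.19 and 0.55 above control in the 3 homozygous libraries. None of 17 endothelial markers changed (0 adjusted over the list alone, median 0.06, camera adjusted p = 0.324), and Pecam1 was at 5.85 ± 0.893 and 6.18 ± 0.860 RPKM. Of 9 pericyte markers 1 rose (0 adjusted over the list alone, median 0.15, camera adjusted p = 0.168), and of 16 meningeal markers 1 fell (1 adjusted over the list alone, median 0.07, camera adjusted p = 0.786). None of 8 choroid plexus markers (0 adjusted over the list alone, median -0.04, camera adjusted p = 0.941) and none of 3 oligodendrocyte lineage markers (0 adjusted over the list alone, median -0.06, camera adjusted p = 0.880) changed. Of 10 erythroid genes, a measure of blood in the dissection, 2 fell, among them the anion exchanger Slc4a1 (2 adjusted over the list alone, median -0.33, camera adjusted p = 0.0572, but 0.00666 with no filter, 0.00405 in a fit of these 2 groups and 0.0308 to 0.0418 without control library 1, homozygous library 1 or homozygous library 2). In all 3 homozygous libraries the erythroid mean lay below that of all 3 controls. The Slc4a1 call was lost without control library 2 (limma adjusted p = 0.102), and also without control library 3, homozygous library 1 or homozygous library 3 and with no filter.

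Of 30 cell cycle genes 22 fell and 0 rose (23 and 0 adjusted over the list alone, median -0.42, camera adjusted p = 1.57e-08, adjusted p = 0.720 with an estimated correlation). The mitotic kinase Cdk1 fell from 68.7 ± 0.822 to 44.6 ± 4.17 RPKM, the replication clamp Pcna from 203 ± 10.1 to 142 ± 6.81 RPKM (SD, n = 3), Aurkb by 0.61 and Aurka by 0.62 on the log2 scale. The proliferation marker Mki67 was at 18.7 ± 2.79 and 14.5 ± 4.78 RPKM (SD, n = 3, limma adjusted p = 0.130, but 0.00473 without homozygous library 2 and 0.0353 with sex in the model). Of 62 replication-dependent histone genes 52 fell and 0 rose (56 and 0 adjusted over the list alone, median -0.53, camera adjusted p = 1.70e-13, adjusted p = 0.720 with an estimated correlation). The linker histone H1f1 was at 3086 RPKM in control and 1940 RPKM in homozygous cortex, and H2bc7, H2bc14 and H2bc13 fell by 0.59, 0.67 and 0.58 on the log2 scale; histone genes are close copies, so reads of 1 can count for another. Of 27 p53 targets 11 rose and 2 fell (11 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.00124, adjusted p = 0.720 with an estimated correlation). The death receptor Eda2r rose by 1.70 on the log2 scale, Ccng1 by 1.38, Sesn2 by 1.09 and the cell cycle inhibitor Cdkn1a by 0.50. Of 15 genes of apoptosis and phagocytosis 4 rose and 5 fell (5 and 6 adjusted over the list alone, median -0.00446, mean 0.01, camera adjusted p = 0.937). The cell death inducer Hrk was higher and Dapk1, Birc5 and Bcl2 were lower. Bcl2 spans 176 kb, and 2 of these 15 genes span at least 100 kb. Ribosomal protein genes rose in 24 of 70 cases and fell in 0 (28 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 1.08e-07, adjusted p = 0.720 with an estimated correlation). Rpl23 was at 325 ± 3.57 and 387 ± 15.6 RPKM (SD, n = 3). Of 68 nuclear genes of the respiratory chain 3 rose and 6 fell (1 and 3 adjusted over the list alone, median 0.01, mean -0.03, camera adjusted p = 0.824). Ndufs4, a subunit of complex I, fell by 1.10.

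The remaining lists did not pass as sets. Of 27 hypoxia and glycolysis genes 5 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.168), led by the glucose transporter Slc2a3 at a log2 change of 1.79 ± 0.12 (SE). Of 21 genes of the integrated stress response 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.324). Asns rose by 0.43, and Ddit3 was at 0.05 (adjusted p = 0.851). Immediate early genes rose and fell in 2 of 9 cases each (2 and 2 adjusted over the list alone, median 0.08, mean -0.02, camera adjusted p = 0.880). Of 13 interferon response genes 3 rose (0 adjusted over the list alone, camera adjusted p = 0.339). Of 23 genes of paraspeckles and DBHS proteins 5 rose and 6 fell (5 and 6 adjusted over the list alone, median -0.01, test direction up, camera adjusted p = 0.937): Pspc1 rose by 1.36 and Matr3, a nuclear matrix RNA-binding protein, by 0.58 on the log2 scale, while Sfpq and the cold-shock gene Rbm3 fell. Of 35 genes of the transcription elongation machinery 3 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.620). The super elongation complex member Mllt3, which spans 263 kb, fell by 0.42, and the elongation factor Supt5 was at 0.09 (limma adjusted p = 0.493). Of 14 abundant non-coding RNAs 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0572, but 0.00864 with sex in the model and 0.00958 to 0.0393 without control library 1 or 2 or homozygous library 2 or 3): Rian, Meg3, Snhg1 and Rmst. Malat1 was at 396 ± 26.8 and 343 ± 26.2 RPKM (SD, n = 3; adjusted p = 0.249). None of the 11 set calls held with an estimated correlation between genes, and at a mean of at least 2 RPKM the Cajal-Retzius, p53 and synaptic lists also missed the threshold, at camera adjusted p of 0.161, 0.0720 and 0.0581. Fry, which does not compare a list with other genes, gave the 11 lists adjusted p from 6.97e-05 (very long neuronal genes) to 0.0472 (microglia). Fry also passed intermediate progenitors (adjusted p = 0.00744) and non-coding RNAs (adjusted p = 0.0239), which missed the camera threshold.

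**Figure D3:**
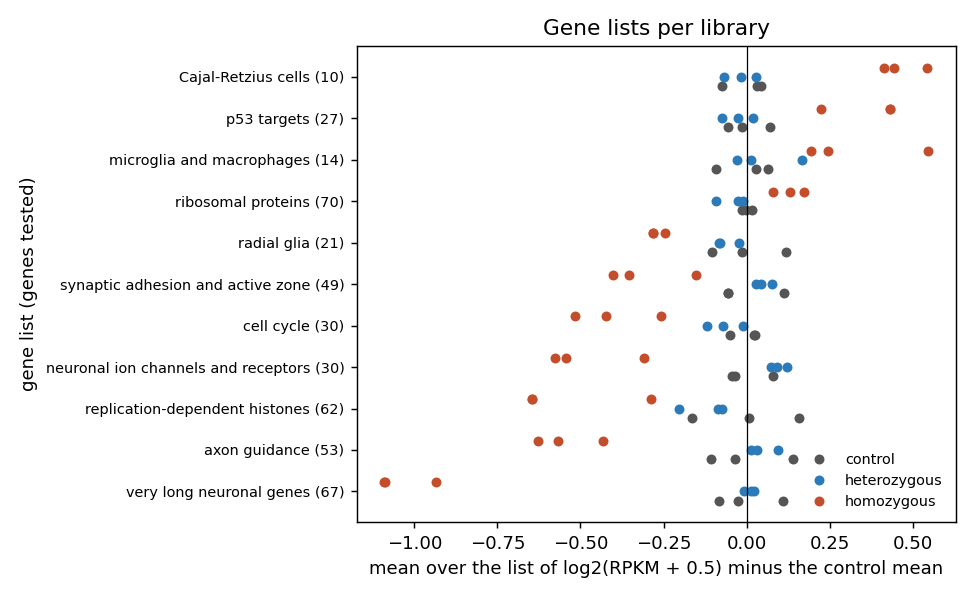
Mean over each gene list of log2(RPKM + 0.5) minus the control mean (horizontal axis) in each of the 9 libraries, for the 11 lists (vertical axis, with the number of genes tested) that passed the camera test with a preset correlation; points are single libraries, coloured by genotype. The homozygous libraries of the very long neuronal genes sit between -1.09 and -0.93 and those of the Cajal-Retzius markers between 0.41 and 0.54, beyond all controls.

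The second comparison asks what loss of 1 Sfpq copy changes. No single gene passed the adjusted threshold in heterozygous against control cortex. Limma called 0 of 12129 genes; 692 genes had an unadjusted p under 0.05, where 606 are expected by chance, and a fit of only these 2 groups called 1 gene. Pspc1 had the smallest adjusted p, 0.214, with a log2 change of 0.39 ± 0.05 (SE); its heterozygous values of 142, 131 and 126 RPKM were above the control values of 100 to 103 RPKM. Matr3 was at 323 ± 5.05 RPKM against 291 ± 2.45 RPKM (SD, n = 3, log2 change 0.15, adjusted p = 0.708). Among the genes that fell most in homozygous cortex, Kcnip1 was at 2.06 ± 0.102 RPKM in heterozygous and 3.59 ± 0.469 RPKM in control cortex (log2 change -0.67, adjusted p = 0.439) and E130307A14Rik at 2.93 ± 0.133 and 4.72 ± 0.291 RPKM (log2 change -0.60, adjusted p = 0.439). Dcc was at 9.47 ± 1.47 and 10.1 ± 0.476 RPKM (adjusted p = 0.981) and Ctnna2 at 29.2 ± 3.64 and 29.0 ± 1.28 RPKM (adjusted p = 0.999). Th, Crabp2 and Calb1, which rose in homozygous cortex, had log2 changes of -0.25, -0.27 and 0.12 with adjusted p of 0.973, 0.727 and 0.998.

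Genes of at least 100 kb had a median log2 change of 0.01 and shorter genes one of -0.01 in heterozygous cortex, a difference of 0.03 (camera p = 0.00505 with a preset correlation, p = 0.605 with an estimated correlation). The long-minus-short value per library was 0.0261 ± 0.0185 in heterozygous cortex (SD, n = 3; exact permutation p = 0.4 against control). With embryo sex in the model, an alternative added after the values were seen, the difference turned to -0.0102. The very long neuronal genes had a median of 0.02 (0 changed, 1 lower adjusted over the list alone, camera adjusted p = 0.340). This list passed upward at a mean of at least 2 RPKM (camera adjusted p = 0.0388) and without control library 3 (camera adjusted p = 0.0424). As sets, 10 of 30 lists passed camera with a preset correlation and 0 with an estimated one (adjusted p = 0.966 for each), although no member of any list changed over all genes. Adjusted over the list alone, 2 radial glia and 1 intermediate progenitor marker were lower, and 1 GABAergic marker and 1 paraspeckle gene, Pspc1, were higher. The upward sets were excitatory neuron markers (median 0.08, adjusted p = 4.34e-04), ion channels and receptors (0.09, adjusted p = 3.01e-04), axon guidance genes (0.03, adjusted p = 0.00793) and synaptic genes (0.05, adjusted p = 0.00873). The downward sets were erythroid genes (median -0.23, adjusted p = 3.01e-04), histones (-0.08, adjusted p = 6.28e-04), cell cycle genes (-0.07, adjusted p = 0.00156), ribosomal proteins (-0.03, adjusted p = 0.00170), the respiratory chain (-0.04, adjusted p = 0.00640) and hypoxia genes (-0.05, adjusted p = 0.0470). All heterozygous embryos were male, so a sex term rests on the control and homozygous embryos, with 1 male control and 1 female homozygous embryo. Sex can therefore not be told from the spread of those single libraries. With sex in the model the list mean turned to 0.0809 for histones, -0.0663 for axon guidance and -0.0317 for synaptic genes. The cell cycle, hypoxia, ribosomal and respiratory chain lists then missed the threshold (camera adjusted p = 0.154 to 0.347). Lists that passed only with sex in the model were lower for endothelial cells (list mean -0.177, camera adjusted p = 8.02e-04), pericytes (-0.183, adjusted p = 0.0298) and radial glia (-0.127, adjusted p = 0.0450). Non-coding RNAs then passed upward (0.113, camera adjusted p = 0.0228). Without heterozygous library 1 the number of lists passing was 3, and without heterozygous library 3 it was 6. The long-gene difference missed the threshold without control library 1, at 0.00771, and without heterozygous library 3, at 0.0134.

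The third comparison sets homozygous against heterozygous cortex. Its largest changes were mostly in genes already named. Th rose by 3.10 and Crabp2 by 2.39 on the log2 scale, Samd3 by 2.35 and Eda2r by 1.76, and Mpped2 fell by 2.46, Ankrd6 by 2.51, Dcc by 2.35, Epha5 by 2.24, Khdrbs2 by 2.12 and the phospholipase Plcb1 by 2.12. Sfpq was at 16.0% of its heterozygous level and fell by 2.62 on the log2 scale (limma adjusted p = 4.39e-09). Pspc1 rose by 0.97 and Matr3 by 0.43. Limma called 3943 of 12129 genes, 1741 higher and 2202 lower in homozygous cortex, and quantile normalization moved this split to 2392 higher and 2078 lower. Of the genes called, 1362 were also higher and 1975 also lower in homozygous against control cortex, where 247 and 438 would be shared by independent lists, and 0 went in opposite directions; both comparisons share the homozygous libraries, which adds to the excess. The log2 changes of the 2 comparisons had a correlation of 0.934 across genes and a covariance of 0.126. In 100 simulations of unchanged groups these were 0.493 and 0.00504. Any homozygous change enters both comparisons, and the simulated groups held no real changes. The simulated values are therefore no reference, and the high correlation is no independent evidence. Genes of at least 100 kb had a median of -0.19 and shorter ones 0.02 (camera p = 5.22e-15 with a preset correlation, p = 0.179 with an estimated correlation), and 721 of the 1640 fell. Of the very long neuronal genes 60 of 67 fell and 1 rose (61 and 1 adjusted over the list alone, median -1.03, camera adjusted p = 5.76e-29, adjusted p = 0.435 with an estimated correlation).

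The same 10 of the 11 list calls of the first comparison, all but radial glia (median -0.06, adjusted p = 0.114), passed here, together with excitatory neuron markers and hypoxia genes. With an estimated correlation 0 of the 12 passed (adjusted p = 0.640 for the 11 besides the very long genes). Axon guidance genes fell in 31 of 53 cases and rose in 6 (32 and 7 adjusted over the list alone, median -0.55, camera adjusted p = 2.11e-07). Excitatory neuron markers fell in 12 of 26 cases and rose in 1 (13 and 3 adjusted over the list alone, median -0.22, camera adjusted p = 0.00732). Cell cycle genes fell in 21 of 30 cases (23 adjusted over the list alone, median -0.39, camera adjusted p = 2.96e-07), with Cdk1 at -0.46. Histone genes fell in 47 of 62 cases (54 adjusted over the list alone, median -0.43, camera adjusted p = 6.24e-11). Ribosomal protein genes rose in 44 of 70 cases (52 adjusted over the list alone, median 0.18, camera adjusted p = 6.18e-11). Hypoxia and glycolysis genes rose in 10 of 27 cases and fell in 1 (10 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.0310), a call lost without homozygous library 1 (adjusted p = 0.05005) or 2 (adjusted p = 0.0654) and with quantile normalization (adjusted p = 0.0558). The p53 targets rose in 13 of 27 cases and fell in 2 (14 and 2 adjusted over the list alone, median 0.20, camera adjusted p = 0.00122). At a mean of at least 2 RPKM the p53 and Cajal-Retzius calls were lost here too, at camera adjusted p of 0.0717 and 0.180. Erythroid genes had a median of -0.08 here, with 0 of 10 changed (camera adjusted p = 0.765).

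Finally, the heterozygous and homozygous changes against control were compared across genes, which are not independent replicates. Their Pearson correlation was 0.210 and their Spearman correlation 0.233 over 12129 genes, and 58.9% of genes had the same sign. Simulated unchanged groups set against shared controls gave means of 0.503, 0.473 and 66.6%. The simulated groups held no real changes, whereas the homozygous changes had an SD of 0.369 over all genes. Real changes in 1 group lower a correlation, so observed values below these means do not show less agreement than chance. The covariance was 0.0103, against a simulated mean of 0.00520 from the shared controls alone, a difference of 0.00515; with 3 control libraries the controls could not be split into 2 parts of at least 2.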

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

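The tests named here were chosen after the values were seen, except that of X-linked genes.

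Xist, the RNA that coats an inactive X chromosome, was at 0.131 RPKM in heterozygous library 3, which also holds Y-linked genes at a mean of 14.4 RPKM. It stood out because the other male libraries reached at most 0.00324 RPKM. It is 4.06% of the mean of the female libraries, and no explanation was tested.

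X-linked genes were higher in homozygous than in control cortex in 20.5% of cases against 14.0% of autosomal genes; with embryo sex in the model the ratio of the shares was 1.53 (Fisher's exact test across genes, p = 1.29e-04). The homozygous group holds fewer females than the control group, so unequal numbers of the sexes would not be a reason for a rise, and the cause was not tested.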

How the results depend on the processing

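The counts of changed genes stayed within 1.5 times in homozygous against control cortex under all settings run, at 3280 (mean of at least 2 RPKM) to 4707 (quantile normalization) genes and 3077 to 3838 without 1 library, and in homozygous against heterozygous cortex, at 3105 to 4470 and 2975 to 3620. Long genes stayed lower and past the camera threshold with a preset correlation in both, from -0.437 (limit of 200 kb) to -0.0809 (limit of 50 kb) in the first. With an estimated correlation 0 lists passed in any of the 3 comparisons. In homozygous against control cortex 7 lists passed at a mean of at least 2 RPKM, where fewer genes are tested. In heterozygous against control cortex, 6 lists passed with quantile normalization and 3 to 13 without 1 library, and 1 gene passed in a fit of 2 groups. Its long-gene difference was 0.0106 with no filter, -0.0102 with sex in the model, 0.00943 against short genes matched on exonic length (the latter 2 added after the data were seen) and 0.00771 to 0.0490 without 1 library. Means of lists that turned to the other sign where a call was involved, all in heterozygous against control cortex, were 0.0164 for ribosomal proteins (quantile normalization), and, with sex in the model, -0.0663 for axon guidance, -0.0317 for synaptic genes and 0.0809 for histones (camera adjusted p = 5.70e-15). Without 1 library axon guidance ran from -0.00658 to 0.116, hypoxia genes from -0.0700 to 0.00672 and non-coding RNAs from -0.0762 to 0.0687. The correlation of heterozygous and homozygous changes was 0.503 in simulated unchanged groups. These groups held no real changes, so the value is no reference for the observed 0.210. A further 75 list values and 224 values of named genes changed sign where neither value was called. The cause of these changes was not tested. Whether the replicate numbers mark a factor shared between groups was not settled. Deviations of same-numbered libraries correlated at 0.404, 0.0651 and 0.321 for homozygous and control. For heterozygous and control these values were -0.0451, 0.0107 and -0.0120. Not every library correlated best with its own number. The replicate block gave 4397, 0 and 4225 genes in homozygous against control, heterozygous against control and homozygous against heterozygous cortex. Scaling moved the median of all genes by less than 0.1. At this depth and spread, 88.2% of changes of 0.5 on the log2 scale were found in simulations of homozygous against control cortex, so smaller changes can be missed.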

Other observations

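The tests of mature transcript length, of the share of neurons, of RNA without a poly(A) tail, of cycling cells and of other cell types were chosen after the results were seen. The tests of transcripts of the same gene and of other groupings of the libraries were fixed before theirs were seen. The bootstrap intervals given below resample genes, not embryos, and take genes as independent. They do not measure the spread between embryos. Genes vary together (estimated correlation 0.273 among the very long neuronal genes), so the intervals can be too narrow.

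Not every long gene fell in homozygous cortex. The 158 genes of at least 100 kb that rose include Plcl2, from 13.3 to 37.7 RPKM, the homeobox genes Pbx3, from 3.53 to 10.2 RPKM, and Meis1, from 2.87 to 7.69 RPKM, the corepressor Rere of 340 kb, from 6.17 to 16.3 RPKM, and the transcription factor St18 of 374 kb, from 5.35 to 11.8 RPKM. Their log2 changes of 1.47, 1.39, 1.28, 1.32 and 1.07 all passed the limma test, and these genes were chosen after their values were seen.

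In heterozygous cortex the smallest unadjusted p values after Pspc1 belonged to Lage3, Mir9-3hg, E130307A14Rik and Kcnip1, chosen after their values were seen. Mir9-3hg, the host gene of a miR-9 copy, was at 6.02, 4.25 and 1.67 RPKM in control, heterozygous and homozygous cortex. Nono, the other DBHS gene, was at 380, 376 and 391 RPKM. None of these heterozygous changes passed the adjusted threshold, the lowest adjusted p being 0.214 for Pspc1.

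Long genes were lower in homozygous embryos. A loss of long mature transcripts, such as by RNA breakage, is argued against: against short genes of matched exonic length the 1640 long genes stayed lower by a median of -0.156 (95% bootstrap interval -0.189 to -0.127). A lower share of neurons as the whole cause is argued against too: very long neuronal genes lay below the 38 neuronal genes under 30 kb by -1.06 (interval -1.31 to -0.72), and those 38 had a median of -0.01, with 7 higher and 8 lower. An effect tied to genomic span itself may underlie the pattern and stays open. In 146 genes the transcript with the larger span was compared with one of at most 0.5 of that span. The larger was lower by a median of -0.0117 (interval -0.0207 to -0.00440), in 93 of 146 genes. The sign-flip permutation p of 0.155 goes with the mean difference of -0.0316, not with the median. A few genes with large differences of either sign, such as Rims2 at 1.32 and Map4 at -1.15, weigh on that mean. Transcripts of 1 gene share exons and so reads, which keeps this comparison of transcripts from deciding.

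Histone genes were lower in homozygous embryos. Poorer recovery of RNA without a poly(A) tail was looked at in 89 small nucleolar, spliceosomal, RNase and telomerase RNAs, 81 of them small nucleolar. Their median log2 change was 0.124 (interval 0.0893 to 0.205), with 12 higher and 1 lower, so these small RNAs did not fall. They are another kind of RNA than histone transcripts, so the test does not decide for the latter. A lower share of cycling cells may account for it: the 30 cell cycle genes, whose transcripts carry a poly(A) tail, had a median of -0.424 (interval -0.504 to -0.349). A change of histone transcription itself stays open and was not tested.

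Microglia and Cajal-Retzius markers were higher in homozygous embryos. A lower share of the main cell types would raise the markers of all others alike. The markers of these 2 types lay above the 41 endothelial, meningeal and choroid plexus markers by 0.278 (interval 0.174 to 0.429). The 2 lists were picked after they were seen to rise, which favours such a difference. The comparison lists had medians of 0.06, 0.07 and -0.04, and their means varied between control libraries with SDs of 0.135, 0.251 and 0.252. Pericyte markers, with a median of 0.15, were not among the 41. The difference therefore does not decide. More of these cells, a change within them and a dissection that held more of the cortical edge stay open as untested explanations. A lower share of the main types stays open too. Reln was not higher (limma adjusted p = 0.149), and abundant choroid plexus Ttr was at 453 RPKM in control and 427 RPKM in homozygous cortex. Levels of single markers do not decide among these explanations.

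Chance in the grouping of libraries was counted over splits of 6 libraries into 3 and 3, which are only 10, too few for a share under 0.05. The real split of homozygous and control libraries gave 4134 genes and the highest other 8, which makes 1 of 10 splits as large. Homozygous and heterozygous libraries gave 3943 against 3, again 1 of 10. Heterozygous and control libraries gave 0 against 1; as no split can give fewer than 0, the 10 of 10 splits that were as large say nothing about chance.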
